A study of Cyanidioschyzon merolae with 64 samples.

How the data were processed

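Total RNA of the unicellular red alga Cyanidioschyzon merolae was hybridised to 64 single-colour microarrays. Per the labels' protocols, cells grew at 42 °C under a 12 h light and 12 h dark cycle, 100 ng of RNA was reverse transcribed with oligo-dT primers, and the cRNA was labelled with Cy3. The arrays came from 8 cultures sampled at 8 times each. In the CDKA experiment 2 wild-type cultures were grown beside 2 cultures of HA-CDKA-cKD, and in the RBR experiment 2 other wild-type cultures were grown beside 2 cultures of RBR-KO. The design text of the series states that each mutant culture was grown together with a wild-type culture and that both pairs of an experiment were grown 1 month apart, so the pair was a term of the model. For each gene the difference between both cultures of a strain in an experiment was averaged over the 8 times. Across genes it correlated between wild type and mutant at r = 0.713 in the CDKA experiment and 0.143 in the RBR experiment.

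The intensity of each spot was made by the authors' scanner software, Agilent Feature Extraction 12.0.3.1, which subtracted background and removed spatial trends within an array, per the file headers. The deposited intensity values were on a linear scale and not scaled between arrays. A value table by the authors was also deposited. Its intensity values correlated at 0.9945 or more with the scanner values on the log2 scale. Arrays of 1 slide shared their distribution while slides did not (medians from 127.7 to 2039.9). The steps behind that table were not given in the sources used here. No genome build is named in the files.

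The log2 of each processed intensity was taken, the array's 75th percentile was subtracted, spots marked as outliers by the scanner software were dropped, and the spots of a gene (3 for 4715 of 4947 genes) were averaged. Genes were kept when their signal was well above background, by the scanner software's own test, on both arrays of at least 1 of the 32 groups of strain, experiment and time. This left 4849 genes and removed 98. No spot was saturated. The share of spots well above background ranged from 79.8% to 98.7% per array, and the number of arrays limits the precision.

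Each slide held the 8 arrays of 1 culture in order of sampling, and the slides were scanned on 5 days. Both CDKA pairs and pair 2 of the RBR experiment were scanned on a shared day per pair. Pair 1 of the RBR experiment was scanned on different days, and its RBR-KO slide was dim, with a median 75th percentile of 388 units against 1378 on the slide of its wild type. Culture and slide could not be told apart. Nor could sampling time and position on the slide, since each time had the same position on every slide.

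A linear model was fitted in limma 3.58.1 with R 4.3.3 to all 64 arrays, with a mean for each of the 32 groups, a term for the pair of cultures and a shared correlation of 0.541 among arrays of 1 culture (30 residual degrees of freedom). P-values were moderated by empirical Bayes and adjusted by the Benjamini-Hochberg method. A gene was called at an adjusted p under 0.05 and a difference of at least 1 on the log2 scale, which is 2-fold. For changes over the cycle the difference was the range of the time means. For a time course that differed between strains no minimum was set. For differences at single times the p-values were adjusted over all genes and the 8 times together. Night was the mean of 0, 16, 20 and 24 h, and day that of 4, 8, 12 and 28 h. Errors of log2 differences are standard errors of the model. For differences between times they rest on the spread of arrays and do not measure separately how cultures vary in that difference.

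Sampling began 30 min before light on, at 0 h. The second-day contrast set 24 and 28 h against 0 and 4 h. Peak time was the highest of 6 clock times, with 0 and 24 h, and 4 and 28 h, averaged. Classes by peak time were taken from the wild type of the experiment that was not being compared. The classes by peak time, the sets of CMV and CMW loci and the overlaps of lists were chosen after the values were seen. The other comparisons, their tests and thresholds were fixed before the data were examined.

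The array files and the reference table of assembly ASM9120v1 gave locus tags with no gene products, and 4689 of 4947 genes matched the table. The planned tests of gene lists by product, and the report of the CDKA and RBR genes by name, were therefore not run. The table served only for the order of genes along chromosomes, and no coordinates are printed. The planned rule for named genes took the 6 largest called changes per direction that went the same way in every pair. With no products, 2 per direction are printed. Loci outside that rule are said to be chosen after their values were seen. The CMV loci (207 on the array) and CMW loci (34) were tested with limma's camera at an inter-gene correlation of 0.01, beside an estimated correlation and limma's fry, adjusted over both sets in each comparison. In the naming scheme of this genome these prefixes mark the plastid and the mitochondrion.

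A gene below background on all arrays of a group was given a bound for its fold, with the lowest signal well above background on each array as the floor. No size is given where a gene was above background on 8 of 16 arrays of a group or fewer, a limit chosen after the values were seen. Independent lists of the same sizes were used as the reference for overlaps. This reference takes every gene as equally likely to be called, so it is not a test of chance. The HA-CDKA-cKD and RBR-KO comparisons share no arrays.

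The model was tested on simulated data of 4849 genes (seed 1) with 200 genes changed in the mean and 200 others in the night-day difference. For HA-CDKA-cKD minus wild type, the adjusted p recovered 82% of genes changed 1.5-fold, 96% of those changed 2-fold and 100% of those changed 4-fold or 8-fold, of 50 each. With the 2-fold minimum as well, 1 of 50 genes changed 1.5-fold and 26 of 50 changed 2-fold were called. Of 4449 unchanged genes, 53 passed the adjusted p and 3 also passed the minimum difference. In this simulation the 53 made up more than a 0.05 share of the genes passing the adjusted p, even if every changed gene passed. For the change of the night-day difference, 84% of genes changed 1.5-fold and 100% of each larger size were recovered, 25 of the 50 changed 2-fold passed the minimum too and 0 of the 50 changed 1.5-fold did, and of the unchanged genes 10 passed the adjusted p.

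Alternatives were quantile normalization, normexp background correction with an offset of 50, the authors' value table, no filter on dim probes, a filter for signal above background on every array (3856 genes), no replicate block, a replicate block per sampling time, no random block for culture, a mean-variance trend, a 1.5-fold minimum, 1 value per culture, and each pair of cultures left out. With a pair left out, each group of that experiment had 1 array, and the spread came from the other experiment alone (15 residual degrees of freedom). The correlation within a culture was then 0.618 without a CDKA pair and 0.135 without an RBR pair, so the experiments did not vary alike. Counts with a pair left out therefore change with this spread as well as with the pair. A common floor, which raised every value to the highest floor of any array, was added after the data were seen. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.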

Results

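Transcript levels of 4849 genes were followed through a day of light and darkness in 3 strains of Cyanidioschyzon merolae. The strains were the wild type, HA-CDKA-cKD, described by the labels as a conditional knockdown arrested in G1, and RBR-KO, a knockout of RBR, the plant-type relative of the retinoblastoma protein. CDKA is a cyclin-dependent kinase. Each mutant had its own wild type, grown beside it, with 2 cultures of each strain per experiment and 8 samples per culture, 4 h apart. Replicate arrays correlated at r = 0.956 to 0.994 across genes (median 0.987, 32 groups of 2 arrays). All levels are relative to the 75th percentile of the same array, so a change common to most transcripts would not be seen.

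In the wild type, 2634 of 4849 genes (54.3%) changed over the cycle by at least 2-fold. The most frequent peak was 3 h 30 min into the light (4 and 28 h), with 699 of 2893 cycling genes in the CDKA experiment's wild type and 711 of 2595 in that of the RBR experiment. Peaks at 12 h, 30 min before dark, followed with 627 genes in the CDKA experiment, and in the RBR experiment 411 genes peaked then and 525 around the end of the night. Of 2418 genes that cycled in both wild types, 1919 (79.4%) had the same peak time and 96.5% were within 4 h. At night 335 genes were higher and 538 lower than by day, a split of 290 and 298 with normexp correction. The largest falls at night were those of CMN235C, with a log2 difference of -5.43 ± 0.12 (standard error, 4 cultures, limma adjusted p = 9.15e-30), and of CMR293C (adjusted p = 5.02e-27), which was above background on 8 of its 16 night arrays, so no size is given. CMS022C rose most at night, by 4.07 ± 0.15 (adjusted p = 2.28e-23), and CMJ149C rose by 3.83 ± 0.17 (adjusted p = 9.08e-21). Each of these 4 loci moved the same way in 4 of 4 wild-type cultures. Single cultures ranged from -5.88 to -4.80 at CMN235C, from 3.66 to 4.46 at CMS022C and from 3.35 to 5.09 at CMJ149C. The standard errors do not measure this spread between cultures.

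The loci with CMV and CMW prefixes, which mark the plastid and mitochondrial genomes, stood out by a positive night-day difference. In the wild type the median log2 difference, night minus day, was 0.56 for 206 CMV loci and 0.99 for 33 CMW loci, against -0.08 for nuclear genes. Of the CMV loci 28 rose, 3 fell and 175 did not pass, and of the CMW loci 15 rose and 18 did not pass. In HA-CDKA-cKD 68 CMV loci rose and 2 fell (median 0.73), and 11 CMW loci rose (median 0.82). In RBR-KO 15 CMV loci rose and 5 fell (median 0.31), and 5 CMW loci rose (median 0.65). Over all 4849 genes 335 rose in the wild type, 244 in HA-CDKA-cKD and 368 in RBR-KO. The wild-type counts are for the mean of both experiments. A change of the night-day difference from the paired wild type was called at 0 of 206 CMV and 0 of 33 CMW loci in each mutant. The median change at CMV loci was 0.22 in HA-CDKA-cKD and -0.32 in RBR-KO, with 163 and 7 of 206 loci above 0. As a set, these changes had camera adjusted p = 9.17e-07 and 1.99e-13 at the preset correlation. With an estimated correlation camera gave 0.534 and 0.210, and fry gave adjusted p = 0.0742 and 0.00276. At CMW loci fry gave adjusted p = 0.513 and 0.225. A small shift of the CMV loci as a set therefore stays possible. Camera gave adjusted p = 8.62e-11 for CMV and 5.18e-10 for CMW in the wild type at the preset correlation. Both calls were lost with an estimated correlation, at adjusted p = 0.149 for each set. So were those in HA-CDKA-cKD (adjusted p = 0.0540 for each) and RBR-KO (adjusted p = 0.535 for CMV and 0.314 for CMW). Fry gave adjusted p = 1.88e-11 for CMV and 3.03e-15 for CMW in the wild type. It gave 9.80e-11 and 4.51e-11 in HA-CDKA-cKD, and 0.00438 and 7.71e-09 in RBR-KO. Neither test took in the correlation among arrays of 1 culture. Without pair 1 of the CDKA experiment 7 CMW loci rose in the wild type, and without pair 1 of the RBR experiment 3 rose in RBR-KO. The labelling primed with oligo-dT.

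Most genes with a night-day difference in the wild type kept its direction in both mutants, though many of them were not called there. The comparison with HA-CDKA-cKD, labelled as arrested in G1, bears on how far diel transcript changes depend on progress through the cell cycle. That is the question in the title of the series. The labels name no arrest for RBR-KO, so its values do not bear on that question in the same way. Of 775 genes that differed between night and day in the wild type of the RBR experiment, 734 (94.7%) had the same sign in HA-CDKA-cKD and 435 were called the same way, while its own wild type had the same sign at 99.9% and 671 called. For 983 such genes from the wild type of the CDKA experiment, 898 (91.4%) had the same sign in RBR-KO and 485 were called the same way, against 99.8% and 671 in its own wild type. The difference was altered from that of the paired wild type at 103 of the 775 genes in HA-CDKA-cKD (172 without pair 2) and at 119 of the 983 in RBR-KO. Across these genes, which are not independent replicates, the mutant's difference had a slope of 0.73 on that of its own wild type for HA-CDKA-cKD (r = 0.889, rho = 0.854) and 0.76 for RBR-KO (r = 0.856, rho = 0.807). Genes higher at night had a median of 0.99 in HA-CDKA-cKD against 1.39 in its wild type, and of 1.06 in RBR-KO against 1.16. Those lower at night had -1.14 against -1.46 and -0.92 against -1.20. In RBR-KO 371 of 375 genes higher at night and 527 of 608 lower at night had the same sign, and in HA-CDKA-cKD 279 of 306 and 455 of 469. Over all genes, 244 rose and 446 fell at night in HA-CDKA-cKD, and 368 rose and 389 fell in RBR-KO. Quantile normalization gave 297 that rose and 336 that fell in HA-CDKA-cKD, the authors' value table gave 315 and 370, and normexp correction turned the split in RBR-KO to 264 and 252. Over the cycle 2009 genes changed in HA-CDKA-cKD and 2557 in RBR-KO.

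The night-day difference itself was altered at 173 genes in HA-CDKA-cKD and at 249 genes in RBR-KO (94 and 148 under normexp correction, 104 and 144 with the strict filter). In RBR-KO most altered genes moved towards night, with 227 higher and 22 lower (208 and 40 without pair 2), while in HA-CDKA-cKD 78 were higher and 95 lower, a split that turned to 93 and 83 with quantile normalization and to 52 and 42 with normexp correction. CMF173C changed by 3.77 ± 0.18 in RBR-KO (limma adjusted p = 5.10e-18) and CMD025C by 3.63 ± 0.20 (adjusted p = 1.20e-16). CMS022C, the locus with the largest rise at night in the wild type, changed by -2.42 ± 0.30 in RBR-KO (adjusted p = 3.72e-08), and CMO087C changed by -1.82 ± 0.15 (adjusted p = 5.06e-12). In HA-CDKA-cKD the difference fell by 3.54 ± 0.32 at CMT284C (adjusted p = 1.24e-10) and by 3.51 ± 0.27 at CMB013C (adjusted p = 4.27e-12). It rose by 2.49 ± 0.25 at CMS058C (adjusted p = 9.21e-10) and by 2.32 ± 0.15 at CMI192C (adjusted p = 3.50e-14). CMT284C was above background on 9 of 16 HA-CDKA-cKD arrays, so its size is uncertain. Each of these changes had the same sign in 2 of 2 pairs. With every array raised to a common floor, the change was 0.64 at CMS058C and -0.56 at CMO087C, under the 2-fold minimum. Without pair 2 of the CDKA experiment the HA-CDKA-cKD count was 286, with 149 higher and 137 lower, and without pair 1 it had 63 higher and 63 lower.

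HA-CDKA-cKD had the most lower genes among those that peak late in the light. Among 411 genes with a peak at 12 h in the other experiment's wild type, 195 (47.4%) were lower than in the paired wild type at 12 h and 3 were higher, with a median log2 difference of -0.91. At 4 h the same class had 5 lower and 12 higher (1 and 2 without pair 1, 2 and 2 without pair 2). The median range of these genes over the cycle was 2.33 in the wild type and 1.16 in HA-CDKA-cKD. It was also smaller in HA-CDKA-cKD in the other classes. There it went from 1.31 to 1.01 (0 and 24 h), 1.46 to 1.14 (4 and 28 h), 1.71 to 1.30 (8 h), 1.54 to 1.10 (16 h) and 1.47 to 1.17 (20 h). The 12 h class had the largest range in the wild type, so a fixed 2-fold minimum could pass more of its genes. Of the 422 genes that peak at 8 h, 87 were lower at their peak, as were 71 of the 329 that peak at 16 h. For a class with 2 peak times, a gene had to be lower at both, a stricter rule than for the other classes. Among the 711 genes that peak at 4 and 28 h, 9 were lower at both (12 at 4 h, 11 at 28 h). Among the 525 that peak at 0 and 24 h, 12 were lower at both (13 at 0 h, 31 at 24 h). Without pair 1 or pair 2 the 12 h class had 148 or 142 lower at its peak, the 8 h class 48 or 58, the class of 4 and 28 h 4 or 3 and that of 0 and 24 h 4 or 7.

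**Figure D1:**
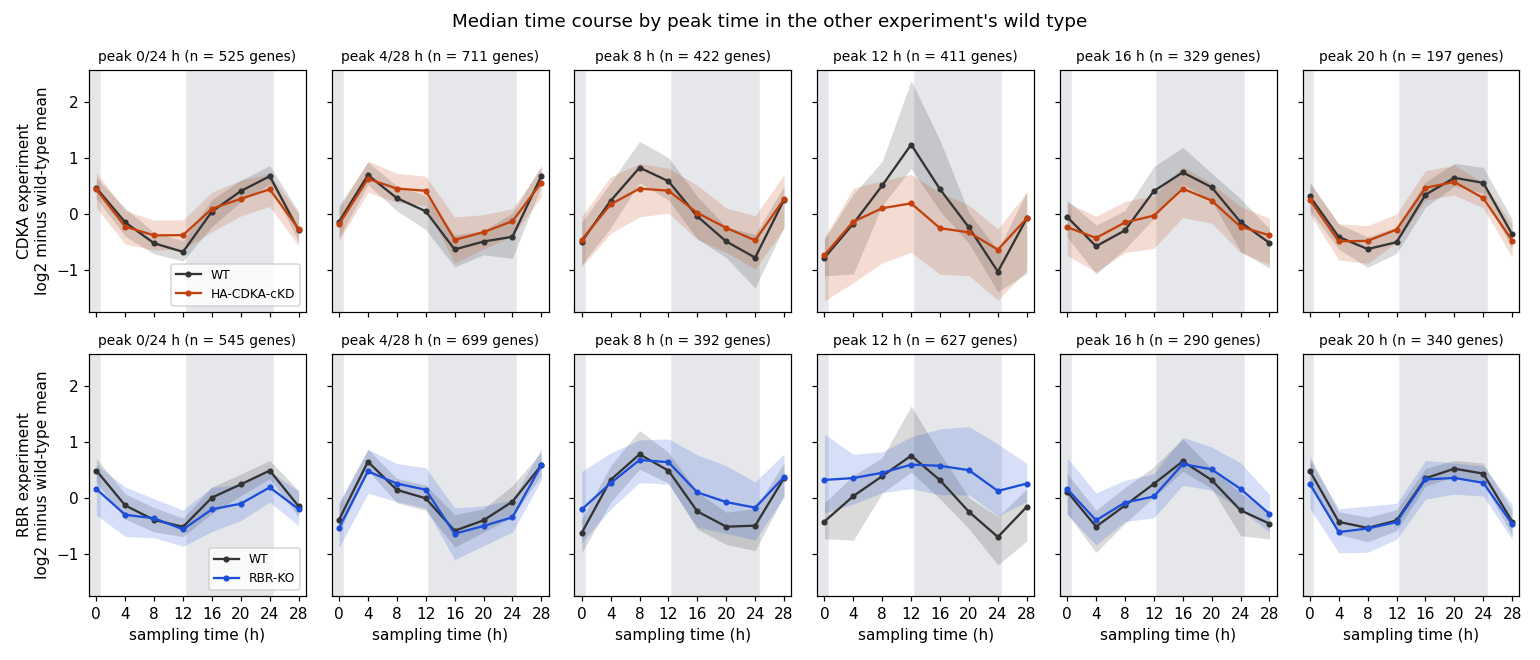
Median time course of genes grouped by peak time in the other experiment's wild type (log2 minus the gene's mean in its own wild type, bands from the lower to the upper quartile across genes, night shaded). For the 411 genes that peak at 12 h, the median range was 2.33 in the wild type and 1.16 in HA-CDKA-cKD. It was smaller in HA-CDKA-cKD in the other classes as well.

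Averaged over the 8 times, 65 genes were higher and 214 lower in HA-CDKA-cKD than in its wild type, with 32 and 108 under normexp correction, 53 and 131 with the common floor and 149 in all with the strict filter. At single times 931 genes differed at 1 time or more (616 under normexp correction), most at 12 h, with 193 higher and 378 lower. At 4 h 64 were higher and 63 lower. The time course differed at 2309 genes (1094 without a random block for culture). CME119C and CMR412C were above background on 16 of 16 paired wild-type arrays, on 48 of 48 arrays of both wild types and the other mutant together and on 0 of 16 HA-CDKA-cKD arrays. Relative to the array floor, CME119C was at least 48.8-fold lower (limma adjusted p = 6.36e-24) and CMR412C at least 34.6-fold lower (adjusted p = 2.70e-12). CME119C was chosen after its values were seen. CMN064C was also lower in HA-CDKA-cKD (adjusted p = 9.87e-12), but it was above background on 2 of 16 mutant arrays, so no size is given. The locus tag of CDKA is not given in the sources used here, so no locus could check the label. CMR293C rose by 1.93 ± 0.43 (adjusted p = 0.000961), and CMT471C also rose (adjusted p = 0.000768) but was above background on 8 of 16 paired wild-type arrays, so no size is given. Both rose in 2 of 2 pairs, but both calls ended when either pair of cultures was left out (log2 differences of 2.15 and 1.72 at CMR293C, limma adjusted p from 0.139 to 0.411), under normexp correction and with a common floor. Leaving out pair 1 gave 24 higher and 102 lower for the mean, 43 and 255 at 12 h and 12 and 23 at 4 h, and leaving out pair 2 gave 36 and 107, 78 and 242, and 12 and 26. Without pair 1 or pair 2 the counts were 402 or 600 at any time and 489 or 1075 for the time course.

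In RBR-KO, many genes of the 12 h peak were higher than in the wild type through the later night and the morning. Among 627 genes with a peak at 12 h in the other experiment's wild type, 218 were higher than in the paired wild type at 20 h. At 24 h 246 (39.2%) were higher and 2 lower, and at 0 h 215 (34.3%) were higher and 2 lower, with a median log2 difference of 0.73. The rise was not confined to this class. At 0 h 99 of 392 genes of the 8 h class were higher (25.3%) and 9 lower. At 24 h 64 of 290 genes of the 16 h class were higher (22.1%) and 0 lower. The class of 0 and 24 h went the other way, with 19 of 545 higher and 60 lower at 0 h. At 12 h itself 6 genes of the 12 h class were higher and 144 lower. Of 2079 genes that cycled in RBR-KO and in its wild type, 57.3% had the same peak time, 291 peaked 8 h later in RBR-KO and 70 peaked 8 h earlier. Without pair 1 or pair 2 the 12 h class had 213 or 290 higher at 24 h and 205 or 235 at 0 h, and without pair 2 it had 51 higher at 12 h and 12 lower at 0 h.

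Averaged over the 8 times, 229 genes were higher and 76 lower in RBR-KO than in its wild type. The counts were 139 and 32 under normexp correction, 131 and 58 with the common floor and 142 and 69 without the replicate block. With the strict filter 176 differed in all. CMR234C rose by 3.37 ± 0.23 on the log2 scale (limma adjusted p = 3.46e-13) and CML181C by 3.34 ± 0.36 (adjusted p = 1.71e-08). CMT038C was above background on 16 of 16 paired wild-type arrays, on 48 of 48 arrays of both wild types and the other mutant together and on 0 of 16 RBR-KO arrays, and was at least 19.9-fold lower (adjusted p = 4.22e-13). CMD006C, CMP170C and CMR257C, chosen after their values were seen, were also above background on every paired wild-type array and on 0 of 16 RBR-KO arrays. They lay near the floor, at least 1.27-fold lower for CMD006C and at least 1.88-fold lower for CMP170C, with no fold given for CMR257C. The mean difference of CMD006C did not pass the 2-fold minimum. CMP170C and CMR257C were also called lower in HA-CDKA-cKD, by -1.42 ± 0.39 and -1.55 ± 0.26, so their fall was not particular to RBR-KO. CMI166C was also lower (adjusted p = 2.99e-14), but it was above background on 6 of 16 RBR-KO arrays, so no size is given, and each named locus moved the same way in 2 of 2 pairs. The locus tag of RBR is not given in the sources used here. At single times 1148 genes differed, with a maximum at 0 h of 452 higher and 221 lower, and the time course differed at 2150 genes (1046 without a random block for culture). With quantile normalization the split of the mean was 178 higher and 110 lower. Without pair 1, whose RBR-KO slide was dim and scanned on another day than its wild type, 203 genes were higher and 48 lower for the mean, and without pair 2, which was scanned on 1 day, 585 were higher and 197 lower, with 765 higher and 512 lower at 0 h. The counts without pair 1 and without pair 2 were 1070 and 2265 at any time, and 1171 and 1565 for the time course.

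**Figure D2:**
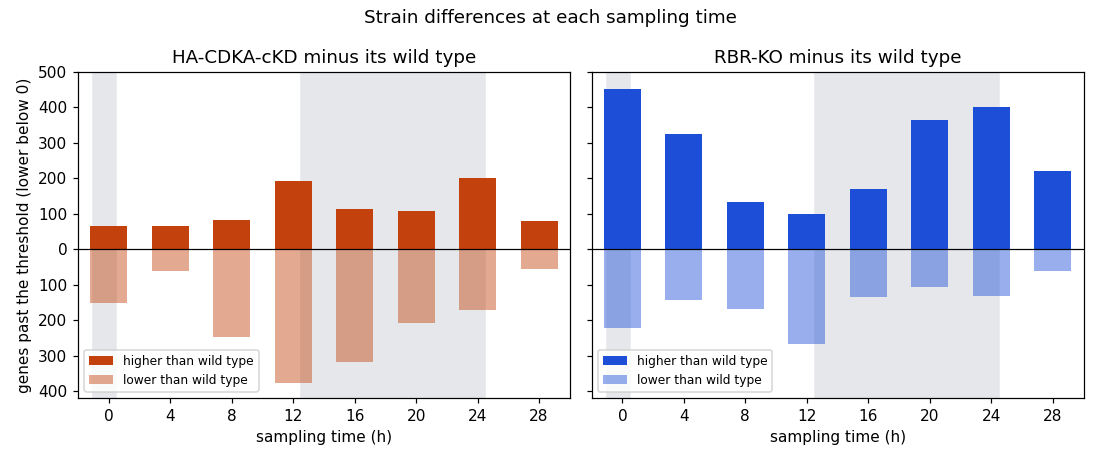
Number of genes past the threshold at each sampling time in each mutant against its own wild type, higher above the axis and lower below it (night shaded, 2 cultures per strain). HA-CDKA-cKD had most lower genes at 12 h (378), and RBR-KO had most higher genes at 0 h (452).

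In the mean of the 8 times, the mutants differed in opposite directions at a shared set of genes. This did not hold at 12 h, where 186 genes were lower in both mutants (122 without pair 2 of the CDKA experiment), against 20.9 for independent lists. Of the 214 genes lower in HA-CDKA-cKD and the 229 higher in RBR-KO, 111 were the same, against 10.1 for independent lists of those sizes. The group had 43 genes with normexp correction, 51 with the strict filter, 53 with the common floor and 55 without the replicate block. In the wild type of the CDKA experiment, 86 of the 111 peaked at 12 h, 14 at 16 h, 9 at 8 h and 2 at 0 and 24 h, and in that of the RBR experiment 75, 19, 15 and 2 did. CMB085C, chosen after its values were seen, is an example. At 24 h it differed by -1.89 ± 0.35 in HA-CDKA-cKD (limma adjusted p = 0.000143) and by 5.34 ± 0.35 in RBR-KO (adjusted p = 2.50e-13), while at 8 h it was lower in both, by -6.53 ± 0.35 (adjusted p = 4.97e-16) and -1.44 ± 0.35 (adjusted p = 0.00280). The reverse group, higher in HA-CDKA-cKD and lower in RBR-KO, held 0 genes against 1.02 for independent lists. In both mutants 18 genes were lower (3.35 for independent lists) and 8 were higher (3.07), with 5 and 3 under the strict filter, 10 and 3 with the common floor and 7 and 0 with normexp correction. CMI166C, of the 18, differed by -4.38 ± 0.31 in HA-CDKA-cKD, where it was above background on 15 of 16 arrays. CMC178C, chosen after its values were seen, was above background on 8 of 16 HA-CDKA-cKD arrays and on 2 of 16 RBR-KO arrays, so no size is given. A test of the difference between the effects passed at 435 genes, with 109 higher and 326 lower in HA-CDKA-cKD relative to RBR-KO (168 and 259 with quantile normalization), at 275 genes without the replicate block or with 1 value per culture, at 274 under normexp correction and at 285 with the strict filter. Without pair 1 or pair 2 of the CDKA experiment this count was 196 (37 higher and 159 lower) or 231 (60 and 171), the group of 111 was 43 in each case, the 18 were 10 or 8 and the 8 were 2 or 1. Without pair 2 of the RBR experiment the count was 1061 (307 and 754), 15 genes were higher in both mutants and 2 were in the reverse group.

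**Figure D3:**
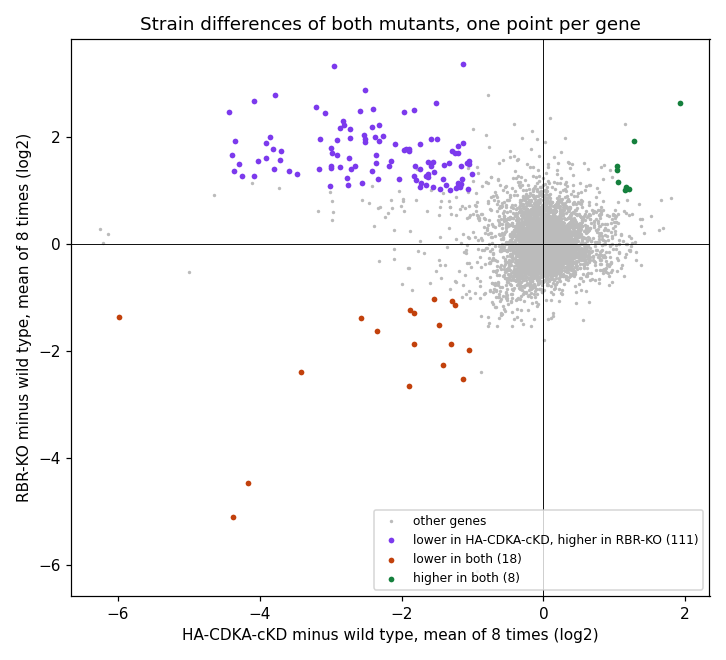
Difference of each gene from its own wild type, averaged over the 8 times, in HA-CDKA-cKD (horizontal) and RBR-KO (vertical), on the log2 scale. The 111 genes lower in HA-CDKA-cKD and higher in RBR-KO lie at the upper left, and the 18 lower in both at the lower left.

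**Figure D4:**
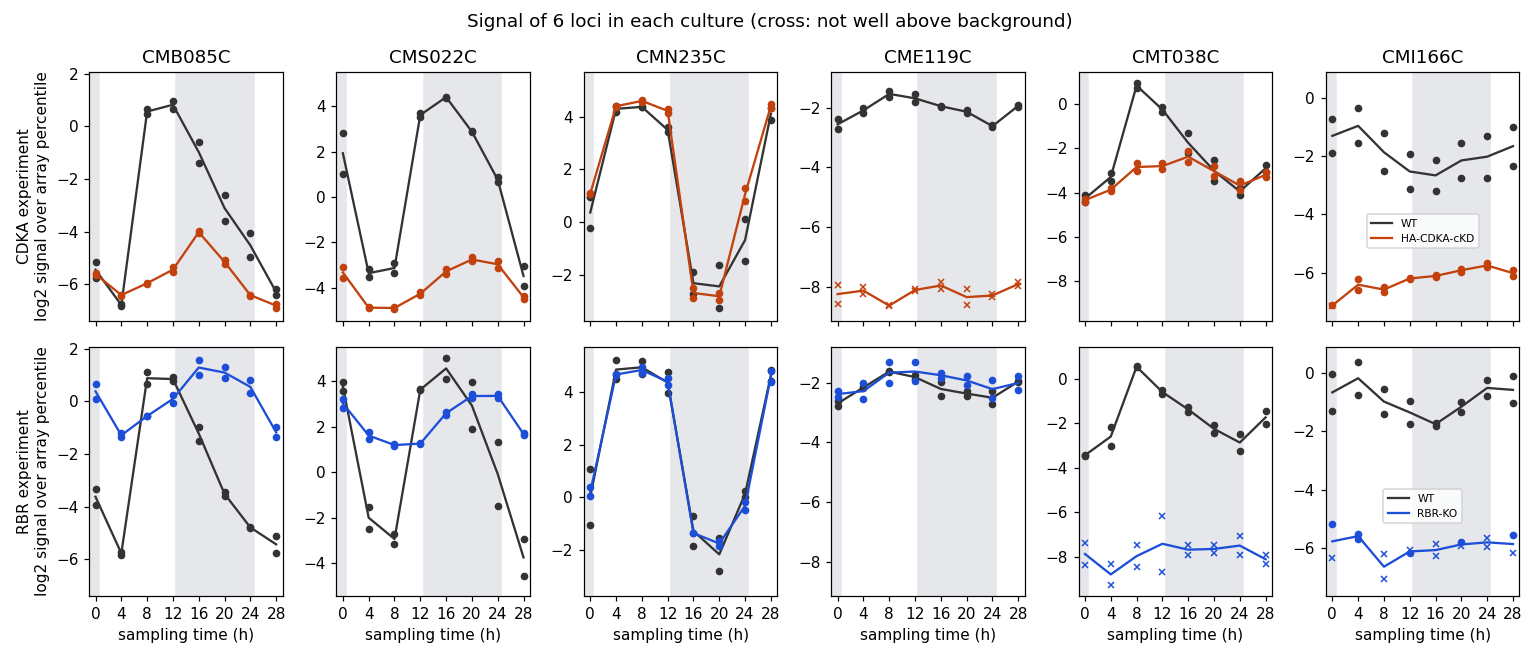
Signal of 6 loci over the day (log2 over the array's 75th percentile), with a point per culture, a line through the mean of 2 cultures, crosses for signals not well above background, and night shaded. CME119C was above background on 0 of 16 HA-CDKA-cKD arrays and CMT038C on 0 of 16 RBR-KO arrays, while CMN235C followed light and darkness in all strains.

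The second morning differed from the one before at few genes. In the wild type 68 of 4849 genes differed between 24 and 28 h and the same clock times a day earlier, of which 64 were lower and 4 higher on the second day. With normexp correction 29 were lower, with the common floor 30, and with the strict filter 41 differed in all. Of the 64, 23 had their peak at 12 h and 19 at 16 h in the wild type of the CDKA experiment. Taken alone, the wild type of the CDKA experiment gave 6 higher and 32 lower, and that of the RBR experiment 18 higher and 135 lower, with 24 lower in both against 0.891 for independent lists. In HA-CDKA-cKD 12 genes were higher and 16 lower, and in RBR-KO 86 were higher and 140 lower. The second-day change differed from that of the paired wild type at 16 genes in HA-CDKA-cKD and 131 in RBR-KO. Without pair 1 or pair 2 of the CDKA experiment HA-CDKA-cKD had 5 higher and 11 lower or 2 and 11, and its count of differing genes was 2 in each case. Without pair 2 of that experiment its wild type had 0 higher and 15 lower, of which 10 were also lower in the other wild type. Without pair 2 of the RBR experiment its wild type had 46 higher, RBR-KO had 163 higher, and the count of differing genes in RBR-KO was 74. The count of 4 higher genes in the wild type ranged from 1 to 11 with a pair left out.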

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

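The test for neighbouring genes among those lower in both mutants was chosen only after the result was seen, as were the common floor and the overlaps of lists. The other tests were set out before their results were seen.

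The effects of the mutants differed at 435 genes, by a test of the difference between groups. The night-day difference was altered at 173 genes in HA-CDKA-cKD and at 249 in RBR-KO, by a test of strain against time of day. The whole time course differed from that of the wild type at 2309 genes in HA-CDKA-cKD and at 2150 in RBR-KO (1094 and 1046 without a random block for culture). The second-day change differed from that of the wild type at 16 genes in HA-CDKA-cKD and at 131 in RBR-KO.

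Of the genes lower in HA-CDKA-cKD, 111 were higher in RBR-KO. Scaling as the whole cause was argued against by quantile normalization, under which 87 genes had this pattern against 6.75 for independent lists. The dim RBR-KO slide was argued against by leaving out its pair, which gave 124 genes against 9.38 (106 against 27.02 without the other pair), and signals near the floor by a common floor, which gave 53 against 3.54. The common floor kept 52 of the 111 genes. It therefore speaks only against signals near the floor as the whole cause, and their part in the other genes stays open. It also stays open that each slide held 1 culture, so that an effect of slide could not be separated from that of culture. A biological explanation, that opposite shifts in cell cycle state may underlie the pattern, is a hypothesis that was not tested here, since no cell counts or cell cycle stages were used.

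In both mutants 18 genes were lower, such as CMI166C and CMC178C. Loss of a stretch of neighbouring genes could have lowered them together, but 0 of the 18 stood next to another of them, and they lay on 10 chromosomes. A background shared by both mutants that their wild types lack, through how the strains were made or a base difference under a probe, stays open and was not tested. No biological explanation was tested.

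CMV and CMW loci had positive medians at night, 0.56 and 0.99 on the log2 scale in the wild type. Probe GC was argued against for the CMV loci, since nuclear genes matched on GC had a median of -0.025 (matches for 85.0% of the loci). The same check was void for the CMW loci, where 60.6% had a match and the matched median was -0.47, so GC cannot be told apart from a mitochondrial effect there. Quantile normalization gave medians of 0.62 for CMV and 1.02 for CMW, which argues against the choice of scaling method as the cause. Like the main scaling it sets all arrays to a common level, so it cannot exclude scaling itself. Before scaling, the wild type of CDKA pair 2 had 75th percentiles of 1602 to 2088 at night and 2002 to 2740 by day. That of RBR pair 2 had 2610 to 4141 and 6475 to 8371. A rise in unscaled signal is therefore not shown. Oligo-dT priming, through which a change in the share of tailed organelle RNA could read as a change in level, stays open beside a biological difference between night and day, and neither was tested.

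Sampling times were shuffled within each culture in 100 draws, the real order included. For changes over the cycle in the wild type 1 of 100 gave as many genes, the real order with 2634 against 993 at most. For night minus day it was also 1 of 100. The real count stood at 873 against 182 in the wild type, 690 against 94 in HA-CDKA-cKD and 757 against 95 in RBR-KO. For these 4 results the share was under 0.05 and the smallest that 100 draws can give. The shuffle cannot tell sampling time from position on the slide, which went together on every slide. For the second-day change 6 of 100 draws gave as many as the real 68 genes, with up to 499, so the share was not under 0.05. Shuffled orders bring day and night differences into that contrast, a structure of the samples, so this test decides nothing about chance. The wild types of both experiments, which share no arrays, had 24 genes that were lower on the second day in both, against 0.891 for independent lists. These times had the same slide positions in both experiments, so the overlap cannot tell the second day from position.

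The 4 cultures of an experiment can be split 2 against 2 in 3 ways, too few for a share under 0.05. Without the replicate block the real split gave the highest count, 1 of 3, in each of 8 results. In HA-CDKA-cKD these were 173 against 3 at most for the altered night-day difference, 230 against 0 for the mean, 2372 against 1 for the time course and 782 against 0 at any time. In RBR-KO they were 249 against 1, 211 against 1, 2186 against 28 and 990 against 12. For the difference between the effects 2 of 18 splits gave as many genes as the real 275. The other, with 288, swapped wild type and mutant in the RBR experiment alone, so that it added the effects instead of subtracting them, and 18 splits are too few for a share under 0.05.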

How the results depend on the processing

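The common floor, the classes by peak time, the medians of the CMV and CMW loci and the overlaps were chosen only after the data were seen. No called value changed sign. The cause of each change was not tested, except that a lower minimum admits more genes and a stricter filter tests fewer (3856). With a pair left out the spread came from the other experiment, so those counts do not show dependence on the pair alone.

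With a 1.5-fold minimum 4012 genes changed over the cycle, 1965, 1685 and 1755 differed between night and day in wild type, HA-CDKA-cKD and RBR-KO, 559 and 582 had an altered night-day difference in HA-CDKA-cKD and RBR-KO, 560 and 810 differed in the mean, 1863 and 2428 at any time, 839 in the difference of effects and 232 on the second day. Normexp correction gave 94 and 148 altered night-day differences, 140 and 171 for the means, 616 at any time in HA-CDKA-cKD, 274 for the difference of effects and 31 on the second day. The strict filter gave 104 and 144, 149 and 176, 285 and 41 in the same order, without a change at any time by over 1.5 times. The common floor gave 184 and 189 for the means and 32 on the second day. Without a random block for culture the time courses differed at 1094 and 1046 genes. The difference of effects passed at 275 genes without the replicate block and at 275 with 1 value per culture. The replicate block moved no other count of calls by over 1.5 times among the 14 planned counts. Without it, though, the 229 genes higher in RBR-KO were 142, and the 111 genes lower in HA-CDKA-cKD and higher in RBR-KO were 55.

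The share of night-day genes with the same sign in HA-CDKA-cKD was 94.3% with quantile normalization, 96.4% with normexp correction, 93.9% in the authors' table, 96.4% with the strict filter and 93.0% with the common floor. In RBR-KO it was 92.5%, 95.02%, 91.7%, 94.5% and 93.2%. With pairs left out it ranged from 94.5% to 94.8% in HA-CDKA-cKD and from 90.7% to 91.3% in RBR-KO.

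With each pair left out in turn, altered night-day differences ranged from 126 to 286 in HA-CDKA-cKD and from 248 to 286 in RBR-KO, the means from 126 to 143 and from 251 to 782, time courses from 489 to 1075 and from 1171 to 1565, any time from 402 to 600 and from 1070 to 2265, and the difference of effects from 196 to 1061. The cycle ranged from 2494 to 2785, night minus day from 704 to 1024 in the wild type, and the second day from 55 to 87.

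Among the loci printed by rule, 181 comparisons with other settings kept their call and 6 lost it, and 44 with a pair left out kept it and 4 lost it. Those that lost it were CMS058C and CMO087C under the common floor, and CMR293C and CMT471C under normexp correction, the common floor and without either pair. Of other values, 313 moved and 1149 did not under other settings, and 182 moved and 166 did not with a pair left out. Normexp correction moved the median night-day difference of all genes from -0.05 to 0.11, and the share of night-day genes that rose in the wild type from 38.4% to 49.3%. Quantile normalization moved the share of higher genes in the difference of effects from 25.1% to 39.3%.

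The probe with the highest signal could not replace the mean, since each gene has 1 probe sequence, and slide as a block equals culture, so neither was run. Alternatives for gene lists were not run for want of products. Signals near background limit RBR-KO most, with 79.8% of spots well above background on the array with the lowest share.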

Other observations

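The overlaps of lists were chosen only after the values were seen. The test of adjacent genes was set out before its result was seen.

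At 12 h both mutants were lower at a shared set of genes. Of 378 genes lower in HA-CDKA-cKD and 268 lower in RBR-KO at 12 h, 186 were the same, against 20.9 for independent lists. Across all 4849 genes, which are not independent replicates, the effects at 12 h correlated at r = 0.579, while the effect of HA-CDKA-cKD at 12 h correlated at -0.405 with that of RBR-KO at 0 h. In the mean of the 8 times the effects correlated at -0.198. Of the 378 genes, 172 were higher in RBR-KO at 0 h, against 35.2 for independent lists. Without pair 2 of the CDKA experiment these overlaps were 122 and 104, and without pair 1 they were 125 and 111.

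The genes lower on the second morning in the wild type of the RBR experiment (135) overlapped those lower in HA-CDKA-cKD (214) by 73, against 5.96 for independent lists. Without pair 1 or pair 2 of the CDKA experiment the overlap was 39 or 47. These experiments share no arrays. That these genes may follow the state of the cell cycle on a given morning is a hypothesis. It was not tested, since that state was not measured here.

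Adjacent nuclear genes had more similar time courses in the wild type than shuffled gene orders, by a small margin. The mean correlation of 3920 adjacent pairs was 0.0356, against a mean of 0.00753 in 100000 shuffled orders, of which 111 were as high (one-sided permutation p = 0.001). For genes 2 steps apart the mean was 0.00797. Neighbours may share regulation to that small degree, and sequence similarity between them was not tested.

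The wild types of both experiments differed from each other at 51 genes that were higher and 109 lower in the CDKA experiment, averaged over the day. Their night-day differences correlated at r = 0.947 across genes, and the median correlation of a gene's time course was 0.909.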
